A study of Mus musculus with 6 samples.

How the data were processed

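Total RNA from the brain without its cerebellum was measured on Affymetrix expression arrays in 3 samples from Gb5-deficient and 3 from wild-type mice, 1 array per sample. Gb5, the product of Gnb5, is the divergent G protein beta subunit that pairs with the R7 family of RGS proteins. The series design describes the 3 samples of each genotype as biological replicates, and the labels describe littermate cohorts matched for age and sex. The replicates were taken as separate animals on that basis, and sex-linked transcripts, given with the results, leave open whether each array holds RNA of 1 animal. The age, the sex of each animal and the strain were not given in the sources used here. RNA was extracted with Trizol and 6 ug was labelled with biotin, per the labels' protocols.

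The deposited table holds normalized log2 expression values, 1 per probe set and array, and the submitters' processing notes name RMA and Partek, with no version given. RMA corrects the background, normalizes the arrays to a common distribution and summarizes the probes of a probe set on the log2 scale. It leaves dim probe sets at low positive values and compresses large fold changes that end near the background. Array scanner files and detection calls were not used here, so no probe set could be called absent. The deposited log2 values ran from 1.91 to 14.4, with array medians between 5.81 and 5.85, and were not normalized again. The number of arrays limits the precision: the median standard error of a log2 difference was 0.123.

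The table held 45101 probe sets. The 64 control probe sets were left out, and the other 45037 were tested without a filter on dim signal. In the platform annotation 34945 of them had 1 gene, 932 had several and 9160 had none listed. Entrez identifiers placed 34741 of the 1-gene probe sets in the RefSeq gene table of mouse assembly GRCm38.p6, and 0 symbols changed. That table was used only for names, chromosomes and the order of genes, because no build was given for the arrays. No gene was named from a probe set with several genes.

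Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (statmod 1.5.0), two-sided, with Benjamini-Hochberg adjustment over the 45037 probe sets and a threshold of 0.05. The fit had 4 residual and 5.05 prior degrees of freedom. Differences are knockout minus wild type on the log2 scale, given with the standard error of the fit. The targeted gene was also compared by an exact permutation test of the group means, for which 3 against 3 arrays give no p under 0.1. On simulated values for the 45037 probe sets, the fit called 10 of 50 probe sets changed 1.5-fold, 35 of 50 changed 2-fold, 49 of 50 changed 4-fold and 50 of 50 changed 8-fold, with 10 calls among unchanged probe sets. These values were drawn independently for each probe set. On them a list of random genes shifted by 0.3 on the log2 scale was called, and 0 of the unshifted lists were. Estimated correlations in the real lists reached 0.737, so this does not show how camera behaves on them.

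Before the data were examined, 37 gene lists were fixed. They covered Gb5 partners and G protein signalling, cell types and regions of the brain, tissues that can contaminate it, neuronal activity, stress, metabolism, sex-linked genes and genes near Gnb5. Of their 775 genes, 690 were measured. Each gene was read through the 1-gene probe set with the highest mean over the 6 arrays, which gave 18193 genes. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 37 lists. Neighbours of Gnb5, 25 annotated genes on each side, were compared with all other genes by Fisher's exact test, two-sided.

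The text names genes by a rule fixed at the same time. It takes every Gnb5 probe set and the R7 complex genes, the 12 genes with the largest rise and the 12 with the largest fall among called probe sets whose groups do not overlap, and up to 4 members of each list with the smallest p. Where fewer than 12 passed in a direction, the smallest p values filled the places, and those genes are said not to pass. Other members or probe sets of these genes are named where a count needs them, chosen after their values were seen. Alternatives covered filters on dim probe sets, 3 further normalizations, trend and robust eBayes, array weights, 1 probe set per gene, other thresholds, other readings of the lists and windows, and leaving out each replicate. Figures were drawn with matplotlib 3.10.9.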

Results

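The series compared the transcriptome of the brain without its cerebellum between 3 samples from mice lacking Gb5 and 3 from wild-type littermates. The 6 arrays were close to one another. Pearson correlations across probe sets, which are not independent replicates, ran from 0.994 to 0.996 between knockout arrays, from 0.995 to 0.996 between wild-type arrays and from 0.989 to 0.996 between the groups. Along the first principal component, with 40.3% of the variance, the knockout arrays lay at -49.8, -5.82 and -8.47 and the wild-type arrays at 32.3, 15.4 and 16.4.

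In the knockouts, the transcript of the targeted gene was far lower, and probe sets of a few genes on its chromosome were lower. A probe set of a photoreceptor gene on another chromosome was much higher. Gnb5 read 3.41 ± 0.361 (SD, n = 3) in knockouts and 9.03 ± 0.258 (SD, n = 3) in wild types. It fell by 5.62 ± 0.193 (SE), 49.1-fold lower, with a limma adjusted p of 4.48e-06. The knockout mean lay at percentile 18.8 of all probe sets and the wild-type mean at percentile 81.6. The exact permutation p for Gnb5 was 0.1, the smallest that 3 against 3 arrays can give. A dim second Gnb5 probe set read 3.70 in knockouts and 4.68 in wild types, a difference of -0.98 ± 0.19 that did not pass (limma adjusted p = 0.173). It passed only without wild-type replicate 6, at -1.23 and an adjusted p of 0.0337. Where either probe set lies relative to the deleted part was not given in the sources used here.

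Of 45037 probe sets, 12 passed the limma adjusted threshold, 2 higher and 10 lower in knockouts, and 8 of the 12 had 1 gene. Guca1b, a calcium-binding activator of photoreceptor guanylate cyclase encoded on chromosome 17, rose by 5.16 ± 0.143, 35.6-fold, from 4.35 ± 0.274 (SD, n = 3) to 9.50 ± 0.0774 (SD, n = 3), with an adjusted p of 1.88e-06. The wild-type mean was not shown to lie above background, so the fold this probe set reads may be understated. It need not hold for the whole transcript. The other Guca1b probe set, with a mean level of 3.65, differed by 0.13 (95% interval -0.13 to 0.40). Trmt112, a partner subunit of several methyltransferases, was 0.82 ± 0.0931 higher with an adjusted p of 0.039. That probe set was dim, at 5.44 in knockouts and 4.62 in wild types. The other Trmt112 probe set, far brighter at 11.8 and 11.7, differed by 0.11 (95% interval -0.15 to 0.38). Leaving out any 1 of the 6 arrays ended the Trmt112 call, at adjusted p values from 0.11 to 0.234, while the difference stayed between 0.80 and 0.84.

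Besides Gnb5, the named genes with a probe set that fell were Tmod3, Tmem30a, Col12a1, Cep162 and Gm19531, all on chromosome 9 with Gnb5. Each value is that of 1 called probe set. Tmod3, a tropomodulin that caps actin filaments, fell by 2.94 ± 0.238, 7.67-fold lower, with a limma adjusted p of 0.00289. Tmem30a, a subunit of phospholipid flippases, fell by 2.52 ± 0.181, 5.72-fold lower. Col12a1, a collagen chain, fell by 2.08 ± 0.148, 4.22-fold lower. Both Tmem30a and Col12a1 had an adjusted p of 0.00115. Knockout means of 3.41 for Gnb5, 3.63 for Tmod3 and 3.62 for Col12a1 were not shown to lie above background, so the folds these probe sets read may be understated. They are no bound for the whole gene, since other probe sets of Tmod3 and Col12a1 fell less or not at all. Cep162, a centrosomal protein of the ciliary base, fell by 1.43 ± 0.163 and Gm19531, a long noncoding RNA that overlaps Gnb5 in the RefSeq table, by 1.17 ± 0.134, both with an adjusted p of 0.039. Of 4 other Tmod3 probe sets, 3 were lower with a 95% interval that excluded 0, at -0.85, -0.70 and -0.62, and the remaining one, the brightest at 9.83 in knockouts and 9.75 in wild types, differed by 0.09. Of 9 other probe sets of Tmem30a, Col12a1 and Cep162, 0 were lower with such an interval, and 1 of Cep162 was higher, by 0.42 (0.12 to 0.73). The other Tmem30a probe sets, all brighter in wild types than the called one, differed by only -0.28 to -0.13. The other Col12a1 probe sets read 4.27, 3.62 and 2.38 in wild types, and another of Cep162 read 4.73. These may be too dim to show a fall. The Cep162 call held among leave-one-out fits only without knockout replicate 3, and the Gm19531 call only without knockout replicate 1. In the other fits, adjusted p values reached 0.284 for Cep162 and 0.27 for Gm19531. Differences there stayed from -1.55 to -1.38 for Cep162 and from -1.18 to -1.08 for Gm19531. Of the 3 called probe sets with no listed gene, the one with the smallest p fell by 3.27 ± 0.105 with an adjusted p of 3.52e-06.

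**Figure D1:**
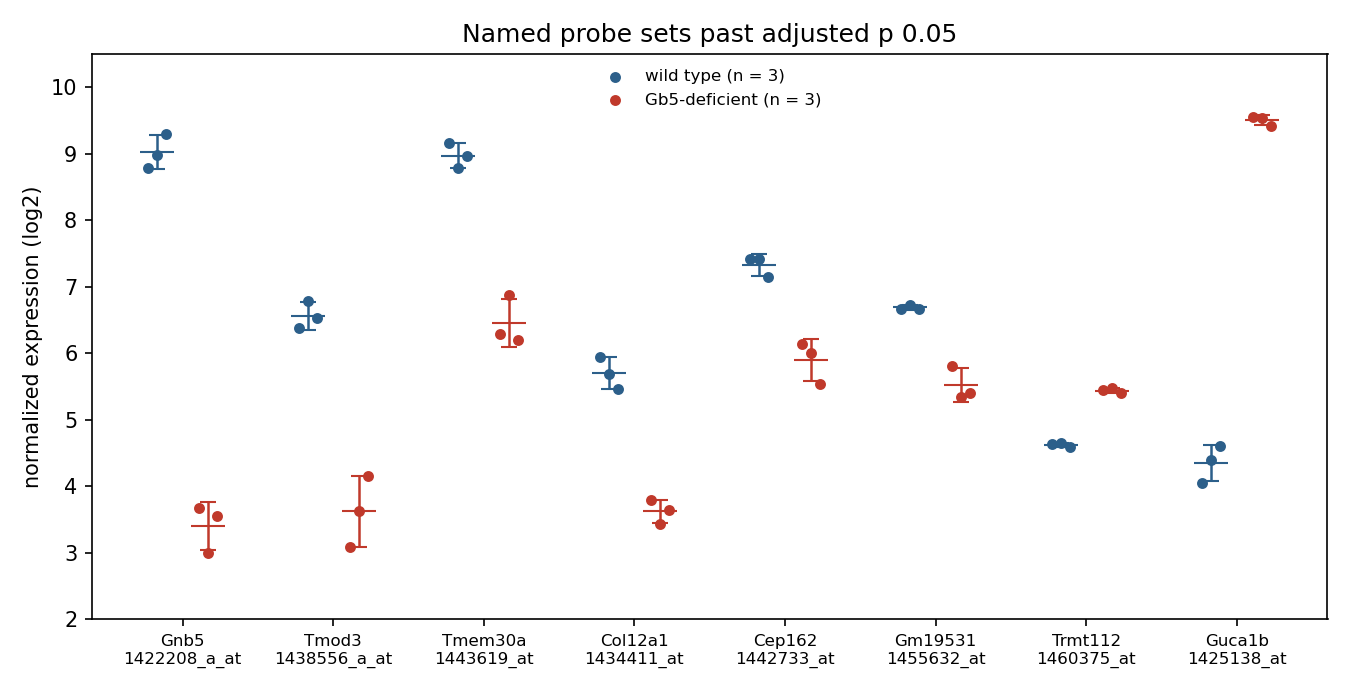
Normalized log2 expression of the 8 called probe sets with 1 gene, named on the axis by gene and probe set, with a point per array, a bar at each group mean and whiskers of 1 SD (n = 3 per group). For Gnb5 the knockout arrays read 3.67, 3.00 and 3.56 against 8.79, 8.98 and 9.30 in wild types, and Guca1b and Trmt112 are the 2 genes with knockout arrays above wild types.

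Calls gathered on the chromosome of the targeted gene. With Gnb5 and Gm19531 left out, 4 of 1889 probe sets on chromosome 9 passed the limma adjusted threshold against 2 of 32992 on the other chromosomes (Fisher's exact p = 0.000118). At an adjusted threshold of 0.1 the numbers were 8 and 22 (Fisher's exact p = 0.000146). In the gene order of GRCm38.p6, Tmod3 lay 10 annotated genes from Gnb5, Col12a1 80, Tmem30a 84 and Cep162 174, all on the same side. Among the 25 genes on each side of Gnb5, 1 of 19 measured genes passed, against 2 of 18173 other genes (Fisher's exact p = 0.00313), and that gene was Gm19531. Because Gm19531 overlaps Gnb5, its fall may read the altered locus itself. The test was not run without it, but no other of the 19 measured genes passed, so its p rests on that transcript alone. With any probe set of a gene counted, 2 of 19 passed against 5 of 18173 (Fisher's exact p = 2.16e-05), since Tmod3 passed through a probe set other than its brightest. Gm19531 was the other of these 2. Counting protein-coding neighbours only, by their brightest probe sets, gave 0 of 42. Both of these settings, and the tests over the whole of chromosome 9, were chosen after the data were seen. At an unadjusted p under 0.05 the numbers were 6 of 19 neighbours, 31.6%, against 15.5% of other genes, a difference that did not pass (Fisher's exact p = 0.103). In the list of genes near Gnb5 written beforehand, 0 of 31 measured genes passed over all probe sets. Adjusted over the list alone, 2 were higher (Lysmd2 by 0.69, Dnaaf4 by 0.44) and 2 lower (Myo5c at -0.59, Aldh1a2 at -0.37).

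**Figure D2:**
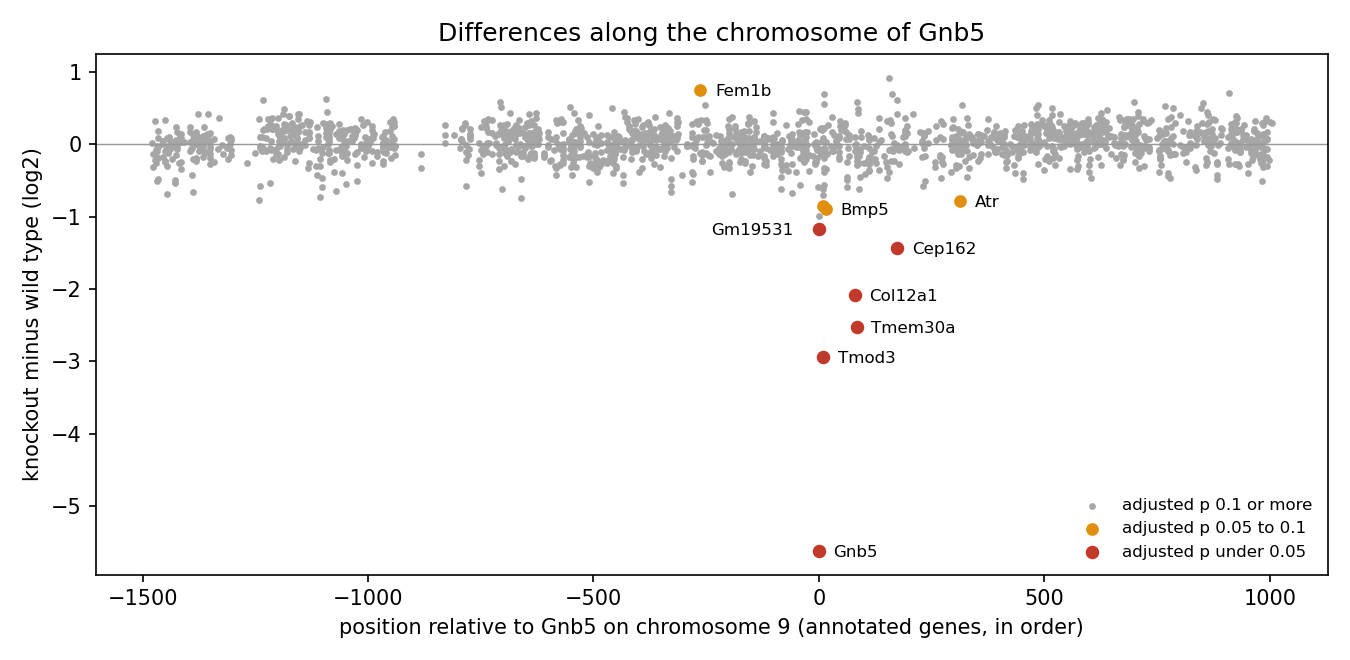
Log2 difference, knockout minus wild type, of each 1-gene probe set on chromosome 9 against the position of its gene, counted in annotated genes from Gnb5. Colours mark the limma adjusted p: Tmod3, Col12a1, Tmem30a and Cep162 lie below -1 on one side of Gnb5, and Fem1b, 263 genes away on the other side, is the only marked gene above 0.

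The remaining named genes had groups that did not overlap and did not pass. Rising values ran from 0.73 for Zfp316 to 1.15 for Arrdc4, an arrestin-domain protein, with limma adjusted p values from 0.0595 to 0.0928. They included Acvrl1, an endothelial receptor of the TGF-beta family (0.90 ± 0.12), Cflar, an inhibitor of caspase-8 activation (0.83 ± 0.114), and Fem1b on chromosome 9 (0.76 ± 0.102). Each value is that of 1 probe set. Other probe sets differed by 0.12 for Arrdc4, 0.40 for Acvrl1 and -0.15 to 0.11 for Cflar. The other Fem1b probe set, far brighter, differed by -0.12. Falling values ran from -0.69 for Dnajc3 to -0.97 for 2610005L07Rik, a RIKEN transcript, with adjusted p values from 0.056 to 0.0721. They included Polb, a base excision repair polymerase (-0.79 ± 0.0988), and on chromosome 9 the DNA damage kinase Atr (-0.79 ± 0.1) and the growth factor Bmp5 (-0.89 ± 0.115). Other probe sets differed by -0.32 to -0.04 for Polb and by -0.35 and 0.03 for Bmp5. Those of Atr, brighter than the named one, differed by 0.16 and 0.18. Over all probe sets, 6493 had an unadjusted p under 0.05, 3644 of them higher in knockouts. With a 1.5-fold size required as well, 479 remained, 169 higher and 310 lower. Groups did not overlap at 9683 probe sets, 21.5% against 10% by chance.

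Apart from Gnb5, the genes of the R7 RGS complex, the known partners of Gb5, did not pass. The list held 9 measured genes, 7 with a positive difference. Rgs6 differed by 0.48 ± 0.139 (limma adjusted p = 0.234), Rgs9 by 0.30 ± 0.11 (0.281), Rgs11 by 0.24 ± 0.154 (0.502) and Rgs7 by 0.17 ± 0.111 (0.515). The membrane anchors Rgs7bp and Rgs9bp differed by 0.07 and 0.19, and the receptors Gpr158 and Gpr179 by -0.09 and 0.04. Other Rgs7bp probe sets differed by -0.18 and -0.20, so its sign depends on the probe set. Rgs9bp and Gpr179, at 3.57 and 4.07 in knockouts and 3.38 and 4.03 in wild types, may be too dim to show a change. Adjusted over the list alone, 1 gene was higher (Rgs6, adjusted p = 0.0315) and 1 lower (Gnb5). This adjustment counted Gnb5, the targeted gene, whose small p lowers the adjusted p of Rgs6. It was not run over the partners alone, where the unadjusted limma p of Rgs6, 0.007, would be too large to pass. The call of Rgs6 thus rests on counting Gnb5. The list's median was 0.17 and its mean -0.47, because of Gnb5, and camera did not call it (adjusted p = 0.948).

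Genes of G protein signalling outside that complex gave 0 calls in limma over all probe sets. Of 14 other RGS genes, 2 were higher and 3 lower at an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone. That gene was Rgs16, at -0.85 ± 0.183. Of 25 heterotrimeric G protein subunits 0 had an unadjusted p under 0.05, with Gnai1 at -0.22 and Gna13 at -0.22. Of 22 genes for GIRK channels and other beta-gamma effectors, 1 did, the channel subunit Kcnj3 at -0.28 ± 0.102. Of 23 Gi-coupled receptors, 3 were higher at that level, among them Sstr3 at 0.54 and Drd2 at 0.35, and 2 lower, Htr1b at -0.26 and Cnr1 at -0.34. Camera called none of these 4 lists, with adjusted p values from 0.509 to 0.756.

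Among markers of brain cell types, camera called 2 lists, both lower, and 0 of their members passed over all probe sets in limma. The oligodendrocyte myelin list had 21 of 22 genes with a negative difference and a median of -0.21 (camera adjusted p = 8.04e-05; adjusted p = 0.899 with an estimated correlation). Its smallest p values belonged to the tight-junction gene Cldn11 (-0.59 ± 0.187), the galactolipid enzyme gene Ugt8a (-0.52 ± 0.202) and Ermn (-0.56 ± 0.221), while Mbp, for myelin basic protein, differed by -0.20 ± 0.103. Adjusted over the list alone, 0 myelin genes passed. The list of meningeal and vascular fibroblast markers had 12 of 13 genes negative and a median of -0.24 (camera adjusted p = 8.04e-05; adjusted p = 0.575 with an estimated correlation). Adjusted over the list alone 2 of its genes were lower, Lox, which cross-links collagen, at -0.69 ± 0.158 and Col3a1 at -0.37 ± 0.0975. Neither list was called by the directional test of fry, with adjusted p values of 0.638 and 0.0863. Its mixed test, which counts differences in either direction and does not compare a list with other genes, called 9 of the 37 lists. The fibroblast list was among them (fry mixed adjusted p = 0.000239) and the myelin list was not (0.338).

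Other glial and inhibitory lists were not called by camera. Microglial markers had 14 of 17 genes positive and a median of 0.19, with Aif1 at 0.35, Csf1r at 0.30 and Cd68 at 0.33 (camera adjusted p = 0.064). Without knockout replicate 1 the camera adjusted p of that list was 0.0179. Over all arrays its adjusted p was 0.665 with an estimated correlation and 0.0605 in the directional test of fry. Astrocyte markers had a median of -0.08, and adjusted over the list alone 2 of 18 were lower, the gap-junction genes Gjb6 (-0.59 ± 0.125) and Gja1 (-0.45 ± 0.105). In the list of GABA and glycine receptors, 2 of 14 were lower on the same basis, Gabra2 (-0.50 ± 0.123) and Glrb (-0.41 ± 0.103). Astrocyte and receptor lists both had a camera adjusted p of 0.064, and an adjusted p of 0.899 with an estimated correlation. Without wild-type replicate 4 camera called both, at 0.00666 and 0.0378, as it did the endothelial, choroid plexus and Gnb5 neighbourhood lists. Medians of the 35 lists not called ran from -0.13 for genes near Gnb5 to 0.52 for pituitary markers, around a median of 0.05 over 18193 genes. In 13 lists the median, the mean and the direction in camera differed in sign.

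**Figure D3:**
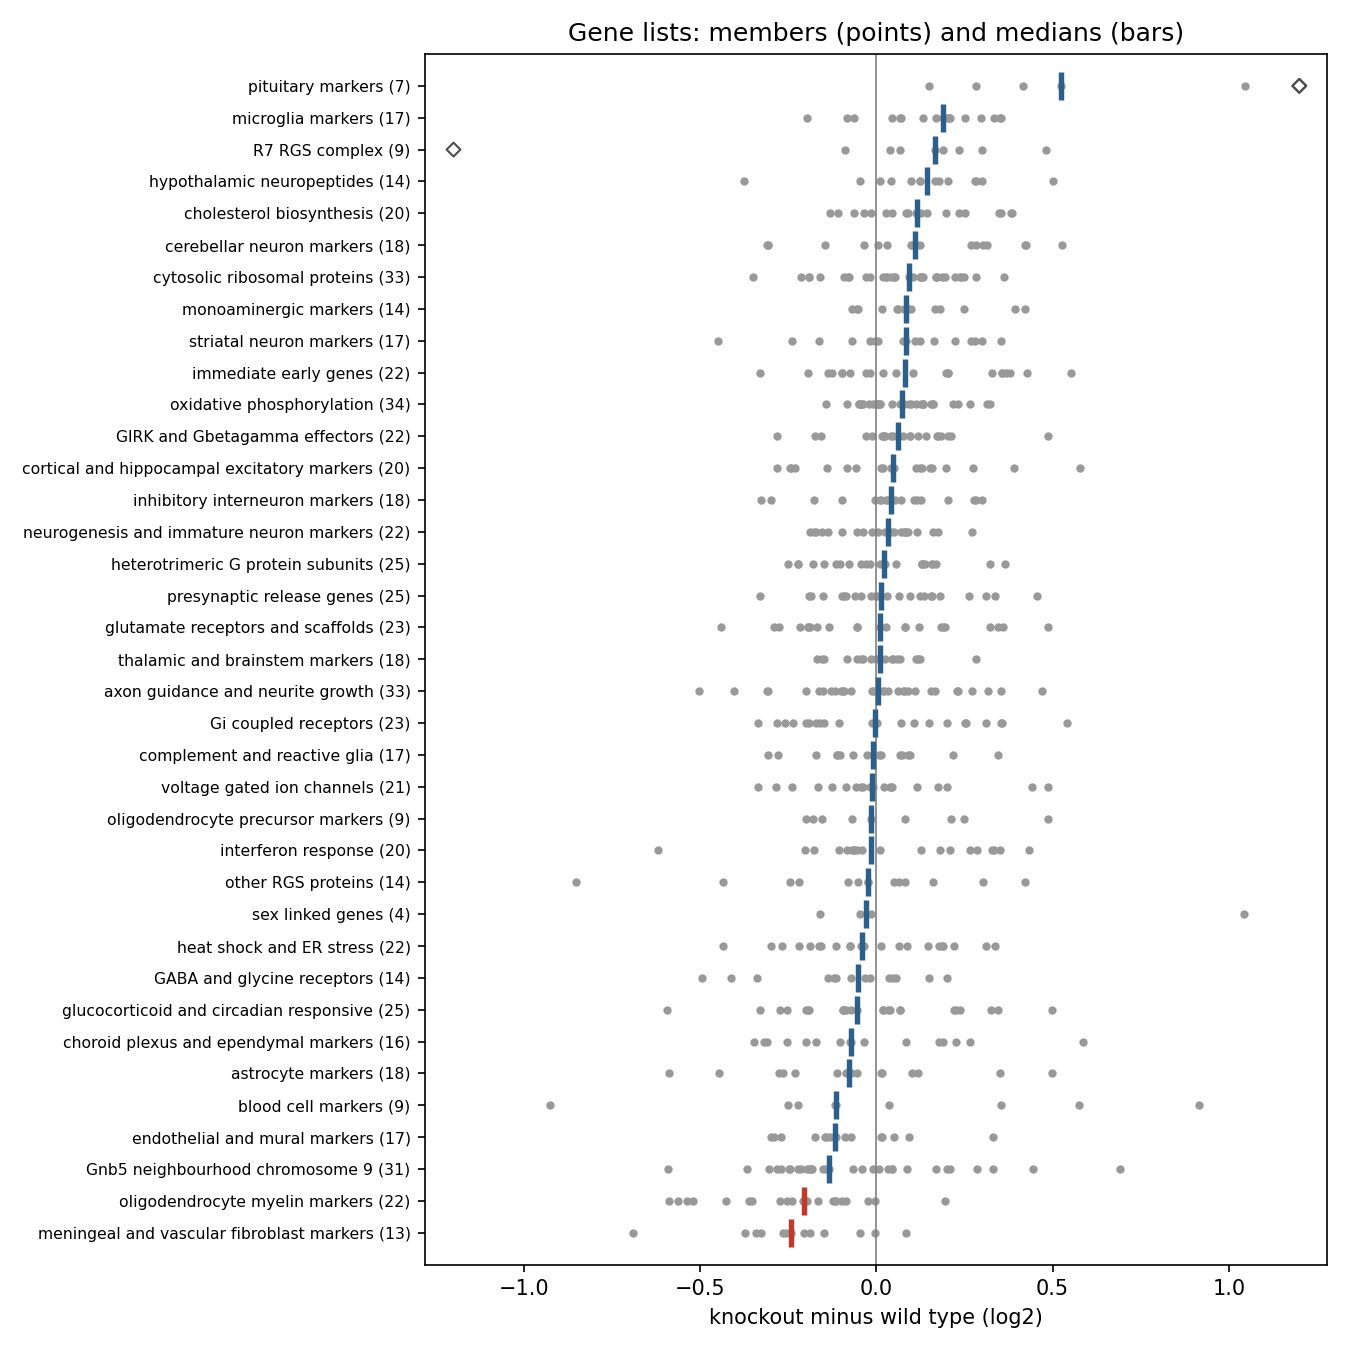
Log2 differences, knockout minus wild type, of the measured genes of the 37 lists (points, number of genes in parentheses) and the median of each list (bars, red where camera with the preset correlation passed). Diamonds at the edges stand for 3 members beyond 1.2 in size, among them Gnb5, and the myelin and fibroblast lists have the lowest medians, at -0.21 and -0.24.

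Markers that can mark the dissection or the sex of an animal differed between arrays within a group. Gh, the pituitary growth hormone gene, read 5.08, 4.67 and 10.6 in the knockouts and 4.70, 4.20 and 6.21 in the wild types. Xist, from the inactive X chromosome, read 10.7, 8.31 and 10.6 in the knockouts and 4.96, 10.8 and 10.7 in the wild types. Eif2s3y, on the Y chromosome, read 2.96, 11.3 and 6.97 in the knockouts and 11.3, 6.05 and 4.05 in the wild types. Knockout replicate 2 thus read high for both Xist and Eif2s3y. The labels give no sex per animal, so whether each array holds RNA of 1 animal was left open, and n counts arrays. With the array of highest Eif2s3y in each group left out, 9 probe sets passed, and 7 of them were among the 12. With the array of highest Gh in each group left out, 8 passed, all among the 12. In the first of these fits Tmod3 no longer passed (-3.03, limma adjusted p = 0.258), nor did Trmt112, Cep162 and Gm19531 in either. Differences in the first and second fit stayed near those over all arrays. They were 0.81 and 0.82 for Trmt112, -1.44 and -1.34 for Cep162, and -1.089 and -1.125 for Gm19531. Both fits were chosen after the data were seen.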

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

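The covariate, the fits without 2 arrays, protein-coding neighbours and any probe set were chosen only after the data were seen. No paired analysis was possible because the groups share no replicate numbers in the labels. Gnb5 kept its call in every fit, from -5.75 to -5.41 with 1 array left out, and its dim probe set lay between -1.23 and -0.85, past the threshold only without wild-type replicate 6. Against 12 called probe sets, fits with 1 array left out called 9 to 12, of which 9 or 10 were among the 12, filters and normalizations called 8 to 16, and Eif2s3y as a covariate 9. The number moved to 23 with trend and robust eBayes (11 shared) and 27 with array weights (12 shared), where the cause was not tested. It was 4 with 1 probe set per gene, where fewer were tested. Looser thresholds gave 44 at an adjusted p under 0.1 and 479 at an unadjusted p under 0.05 with 1.5-fold. Called lists numbered 2 to 7 with 1 array left out, 7 without wild-type replicate 4, 5 without knockout replicate 2, 4 without knockout replicates 1 or 3, 5 with the probe set of largest SD per gene, 8 without the 2 arrays of highest Eif2s3y, and 0 with an estimated correlation or in the directional test of fry. The cause was not tested. The neighbour count turned to 0 in the fixed list and 0 among protein-coding genes, each gene read by its brightest probe set. It was 2 of 19 with any probe set of a gene (Fisher's exact p = 2.16e-05), which adds Tmod3 to Gm19531, the transcript that overlaps Gnb5. Unadjusted, it was 6 of 19 (Fisher's exact p = 0.103). Renormalizing moved the median difference by at most -0.0221. Across alternatives for 31 named probe sets, 446 values stayed on their side of the threshold, most of them uncalled on both, and 24 gained and 27 lost a call. A reversed sign was counted only where the main fit had called the probe set, and 0 were found. No detection calls were used, so dim probe sets could not be parted from background.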

Other observations

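The tests of chromosome 9, of other probe sets of called genes and of oligodendrocyte precursors were chosen only after the results were seen. Lists of neuronal activity and metabolism held members that were higher at an unadjusted p under 0.05, as 15.5% of genes away from Gnb5 differed in either direction, and 0 that passed over all probe sets in limma. Of 22 immediate early genes 5 were higher on that basis, including Fosb at 0.55 ± 0.196, Ier2 at 0.43 ± 0.15 and Egr4 at 0.36 ± 0.129, against 0 lower, with 13 positive and 9 negative differences (camera adjusted p = 0.626). Fosb, Ier2 and Egr4 were dim, at 4.05, 4.94 and 5.39 in wild types, and their means in both groups lay under the median probe set of 5.825. Brighter members differed in both directions, such as Nr4a1 by 0.33 and Egr3 by -0.33, at 8.21 and 10.6 in wild types. Of 20 cholesterol biosynthesis genes 3 were higher, with Hsd17b7 at 0.35, Pmvk at 0.35 and Mvk at 0.39, and 15 had a positive difference (camera adjusted p = 0.337). Of 20 interferon-response genes 2 were higher, the class I gene H2-D1 at 0.43 and the immunoproteasome gene Psmb8 at 0.35, with 10 positive and 10 negative differences (camera adjusted p = 0.976). Of 17 striatal markers, 4 were higher, among them Drd2 at 0.35, and 2 lower, with Pde10a at -0.45 (camera adjusted p = 0.692). Adjusted over the list alone, 2 of 9 blood-cell genes passed in opposite directions, the erythrocyte anion exchanger Slc4a1 at -0.93 and the neutrophil gene S100a9 at 0.91.

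Chance was examined with the 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 12 probe sets in limma and the highest other split 2, so 1 of 10 gave as many. At an unadjusted p under 0.05 the numbers were 6493 and 2165. For lists in camera with the preset correlation, 10 of 10 splits gave as many as the real 2, and the highest other gave 11. That split set knockout replicates 1 and 2 with wild-type replicate 4 against the rest. Median deviations per array of the fibroblast list did not overlap between the groups, at -0.175, -0.09 and -0.07 in knockouts and 0.04, 0.14 and 0.13 in wild types. This was not particular to it, and 10% of lists would part so by chance. The microglial, striatal, GABA and glycine receptor, oxidative phosphorylation and Gnb5 neighbourhood lists did not overlap either.

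The lower probe sets on chromosome 9 were a first pattern to weigh. An effect of missing Gb5 that ignores gene position would spread calls evenly, and the excess on chromosome 9 argued against it as the whole cause (Fisher's exact p = 0.000146). Variants of the stem-cell strain carried with the targeted allele may account for the excess, since all 8 probe sets past an adjusted p of 0.1 lay among the 502 genes nearest to Gnb5 and 0 in the far part (Fisher's exact p = 0.0081). Of 9 other probe sets of Tmem30a, Col12a1 and Cep162, 0 were lower with a 95% interval excluding 0. For Tmem30a the called fall was read by 1 probe set only. Its others, at 9.59 to 11.3 in wild types, differed by -0.28 to -0.13, and no interval went below -0.75. For Cep162, 1 other read 6.67 in wild types and was higher by 0.42, and another was dim. For Col12a1 the other probe sets decide little, because they read only 4.27, 3.62 and 2.38 in wild types. A variant under the called probes is open for these genes. For Tmod3, 3 of 4 others were lower in that way, by less than the called one (-0.85 to -0.62), and the brightest differed by 0.09. That leaves a change in some Tmod3 transcript forms open. A local effect of the altered allele on nearby genes was not tested and stays open, and no sequence or strain data were analysed here.

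The rise of Guca1b was the second. Retinal tissue among the knockout samples would bring other photoreceptor transcripts. Yet the median difference of 18 measured photoreceptor genes was 0.0798 (95% interval over genes -0.0354 to 0.256), far under the rise of 5.16. This interval leaves out the spread between arrays, and only 1 of the 18 lay above the median probe set. At an unadjusted limma p under 0.05, 4 of them differed, all higher, the most being Guca1a at 0.77, a gene that the next test counts too. A chromosome segment that differs between the groups around Guca1b is a candidate explanation, because 30.3% of 33 measured neighbours had an unadjusted p under 0.05 against 15.5% of other genes (Fisher's exact p = 0.0283; a like share around Gnb5, 31.6% of 19 genes, gave 0.103), 9 of them higher, including the adjacent Guca1a at 0.77. Whether the whole transcript was higher cannot be told apart from a rise in 1 form, since the other probe set, at 0.133, read near the dim end in both groups. An effect of the missing Gb5 itself stays open and untested.

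The lower myelin list was the third. Whether knockout replicate 1 alone accounts for it stays open: without that array the median was -0.121, within the spread of the arrays, and camera, which calls lists in every split, decides nothing. A lower share of the whole oligodendrocyte lineage is less favoured by the precursor median of -0.014 over 9 genes, whose 95% interval over genes (-0.18 to 0.249) leaves out the myelin median of -0.21, but it stays open because the myelin-minus-precursor deviation varied as much between arrays, from -0.50 to 0.34 in knockouts and from 0.00 to 0.40 in wild types. A varying share of white matter between dissections may account for it: the median deviation of the list was -0.29, -0.20 and 0.18 in the knockout arrays and 0.06, -0.01 and 0.36 in the wild types, so the groups overlapped (exact permutation p = 0.3, where 0.1 is the smallest that n = 3 per group can give). A difference in myelin genes caused by the genotype stays open.

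Among 64 control probe sets 1 of 2 for the mouse B2 repeat was lower in knockouts by a limma difference of -0.56, with an adjusted p of 0.0251 over the controls, and the other differed by -0.22 (adjusted p = 0.446). Eif2s3y was intermediate in knockout replicate 3 and wild-type replicate 5, at 6.97 and 6.05, while the Y-linked Kdm5d read 3.08 and 2.97 there and 6.79 and 7.21 in the arrays of highest Eif2s3y.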
